A study of Escherichia coli with 4 samples.

How the data were processed

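Colony biofilms of E. coli were sampled as 4 replicates, each with a perimeter and an interior RNA, and each RNA pooled from 3 biofilms grown for 24 h. RNA was reverse transcribed with random primers and labelled with Cy3 or Cy5, per the labels. In replicates 1 and 2 both regions shared a slide, with the dyes exchanged between the replicates, and in replicates 3 and 4 each region had its own Cy3 slide. The single batch the labels and file headers give is this hybridisation type, which coincides with the scan day. It holds both regions in equal number. One strain label in replicate 4 reads TG-2 for the perimeter, and the sample was kept as given.

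The authors quantified the slides with ImaGene 5.1, and the deposited spot values are intensity values per the file headers: mean and median pixel signal and local background, without subtraction. The authors also deposited a table of log2 ratios of perimeter over interior for 43.7% to 49.0% of the spots of a replicate. Its direction was read from its correlation with the scanner values (r between 0.921 and 0.987), and its normalization is not given in the sources used here.

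Of 4608 spots, 322 were controls (274 named internal control and 48 Arabidopsis sequences) and 4286 were gene probes. Gene names came from the platform's probe table, updated by gene identifier to the assembly ASM584v2 of strain MG1655 (4086 probes), or from the spot names (128 matched to that assembly, 71 kept as written). One more probe was named by the platform table alone. The array's own genome build is not given in the sources used here, and names and gene order alone were taken from the assembly. Of 71 genes with several probes, whose ratios were averaged, 24 had probes that differed in sign. None of these is named in the report.

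Signal was corrected for background with normexp (offset 50) in limma 3.58.1 under R 4.3.3. Replicates 1 and 2 were scaled by loess (span 0.3), and the 4 slides of replicates 3 and 4 by quantile normalization. The ratio of perimeter over interior was then taken within each replicate. Probes were kept when the signal exceeded background by 2 SD of background in at least 4 of 8 images, which left 3757 probes and 3682 genes. Median gene-probe signal was between 3.6 and 6.84 times the background. Spots marked by the image software were kept. That choice was made after the agreement between replicates had been seen, where marked and unmarked spots had a mean r of 0.175 and 0.167.

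The mean log2 ratio of each gene was tested with a moderated t test in limma, with the 4 replicates as the units. Genes with an adjusted p (Benjamini-Hochberg) under 0.05 are said to pass, rise or fall. Because the ratio is taken within replicates, the pairing comes from the design. It was checked by correlating the deviations of regions with the same replicate number. For the comparison of hybridisation types the difference between replicates 1 and 2 and replicates 3 and 4 was tested in the same model. The batch is balanced over the regions and was also fitted as a block. Agreement was Pearson's r of log2 ratios over genes for each pair of replicates.

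The 45 gene lists were written before the data were examined, and lists with at least 4 measured genes were tested with camera (preset correlation 0.01, adjusted over lists). They were tested again with an estimated correlation and with fry. A call with an estimated correlation uses the 3 residual degrees of freedom of 4 replicates. The preset test takes its degrees of freedom from the number of genes. Counts adjusted over the list alone correct p over the members of that list. The lists of cold-shock genes, cspA paralogs and genes activated by CRP were written after the first results were seen.

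Genes named in the report follow a rule fixed before the data were examined. It takes the 12 genes of the largest mean ratio in each direction among those past the threshold with 1 sign in all replicates, filled up by the smallest unadjusted p. It adds up to 4 members of each shifted list, and 2 members of smallest p of each other list. For shifted lists with fewer than 4 passing members, those of smallest p in the list's direction filled up the number, and members of the opposite sign that did not pass were left aside. This reading of the rule was adopted after it was seen that few members passed. Other named genes are said to be so.

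The alternatives were no background correction, plain subtraction, median pixel signal, loess on all pairs, median centring, no filter and a filter requiring all images, a dye term, a block for hybridisation type, each format alone, no replicate block, array weights, a robust variance trend, the authors' table, leaving out each replicate, and other thresholds. A filter on the 95th percentile of internal control spots and the removal of marked spots were chosen after seeing the data. The test was tried on simulated data of 3682 independent genes with 200 changed, in 20 runs. It recovered 23.7% of genes changed 2-fold, 59% at 3-fold, 72.9% at 4-fold and 84% at 6-fold, and 4.85% of its calls were false. A shift of 0.5 added to a list was recovered in 20 of 20 runs with the preset correlation, 11 with fry and 0 with an estimated correlation. Over these runs the preset called lists without a shift 3 times, and 2 times in 20 runs where no list was shifted. The simulated genes were independent, so these counts do not cover correlated genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3; statmod 1.5.0 was used with limma.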

Results

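Transcript levels of Escherichia coli were measured in 2 regions of colony biofilms with microarrays that carry probes for nearly all genes of the species. The strain label was TG-1, a laboratory strain of the K-12 line. Biofilms grew for 24 h on nylon membranes laid on Luria agar, a rich medium of peptides and yeast extract, after which the outer perimeter of each was cut away from the interior. Each of the 4 replicates pooled the RNA of 3 biofilms grown separately, and both regions of a replicate came from the same biofilms. In replicates 1 and 2 the regions were hybridised together in 2 dyes, with the dyes exchanged between those replicates. In replicates 3 and 4 each region was hybridised alone in Cy3. In replicate 4 the perimeter RNA carried the strain label TG-2, while the other labels read TG-1. Each of the 8 images held 4608 spots, of which 4286 were gene probes. Between 79.3% and 92.0% of the gene probes stood above local background in the Cy3 images, against 37.8% and 40.4% in the Cy5 images. Control spots carrying Arabidopsis sequences reached between 49.7% and 67.4% of the median gene-probe signal, so that faint genes lay close to the level of spots without an E. coli target. With 4 replicates, the number of arrays limits the precision of every value.

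The first comparison asked which transcripts differed between the perimeter and the interior. Of 3682 genes tested, 28 were higher in the perimeter and 1 was lower. Among these 29 genes the highest ratio was that of ompW (b1256), an outer membrane channel protein, at 8.73-fold (log2 ratio 3.13 ± 0.64, SD, n = 4). Its signal was above background on 3 of 4 interior images, so the fold is not exact. Genes of the flagellar rod and hook, of peptide and sugar uptake, of outer membrane porins and of ATP synthase made up most of the rest. The lower gene was ynfM (b1596), a putative transporter of the major facilitator family, which was lower by 3.16-fold (log2 ratio -1.66 ± 0.34, SD, n = 4). All 29 genes had the same sign in the 4 replicates.

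Genes of flagella and chemotaxis were shifted upward as a group. Of 45 measured members, 6 rose in the perimeter and 39 did not pass over all genes tested. Adjusted over the list alone, 13 passed, all of them higher. The mean log2 ratio of the list was 0.77 ± 0.13 (SD over 4 replicates). Camera with the preset correlation gave an adjusted p = 3.37e-11. That test compares the members with the other genes, and its p does not rest on the spread of the list mean over replicates. Adjusted p of the lists below are from the same test unless another is named. For this list the call held with fry but was lost with an estimated correlation between genes (adjusted p = 0.121 with an estimated correlation). On simulated data of independent genes that test recovered a list shift of 0.5, smaller than the one here, in 0 of 20 runs. The hook protein gene flgE was 7.35-fold higher (log2 ratio 2.88 ± 0.82), and flgD, which encodes the hook cap, was 4.81-fold higher (2.27 ± 0.64). The rod genes flgB and flgC were 3.64-fold and 5.51-fold higher, and flgH, for the outer ring, was 3.79-fold higher (1.92 ± 0.45), a gene named after its value was seen. The gene of the flagellar sigma factor, fliA, was 4.08-fold higher (2.03 ± 0.34).

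Members of the list outside that set were also examined after their values were seen. The flagellin gene fliC had a log2 ratio of 1.14 ± 0.94, and flhD and flhC, the master regulators of flagellar synthesis, had 0.87 ± 0.52 and -0.10 ± 0.20. The motor gene motA had -0.51 ± 0.30 and the chemotaxis gene cheY -0.23 ± 0.69. None of these 5 passed.

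Genes of aerobic energy generation were shifted upward in 3 groups. ATP synthase had the highest list mean, at 1.30 ± 0.15 (adjusted p = 8.39e-09), with all 9 members above 0. The call was lost with an estimated correlation between genes (adjusted p = 0.121 with an estimated correlation), although the estimate itself was below 0 (-0.0343). Of the members, atpH (3.36-fold, log2 ratio 1.75 ± 0.31) and atpB (2.99-fold, 1.58 ± 0.26) rose, 7 members did not pass over all genes, and 7 passed adjusted over the list alone. atpA had a log2 ratio of 1.55 ± 0.34 and atpE 1.56 ± 0.39, both short of the threshold (adjusted p = 0.0518 and 0.0549).

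NADH dehydrogenase I, the proton-pumping entry point of the respiratory chain, had a list mean of 1.00 ± 0.14 (adjusted p = 1.06e-09, and adjusted p = 0.121 with an estimated correlation). All 13 members lay above 0, but 0 passed over all genes (limma), while 10 passed adjusted over the list alone, and 10 had an unadjusted p under 0.05. nuoB had a log2 ratio of 1.26 ± 0.34, nuoE 1.18 ± 0.26, nuoL 1.17 ± 0.31 and nuoC 1.23 ± 0.55. The cytochrome oxidases had a list mean of 0.74 ± 0.37 (adjusted p = 0.000609, and adjusted p = 0.409 with an estimated correlation). They did not pass with fry (adjusted p = 0.0772). Of 9 members, 0 passed over all genes (limma, 5 at an unadjusted p under 0.05) and 5 passed adjusted over the list alone, all in the operon of cytochrome bo, the oxidase used at high oxygen. cyoA stood at 1.68 ± 0.55, cyoC at 1.58 ± 0.37, cyoB at 1.38 ± 0.32 and cyoE at 1.05 ± 0.34 on the log2 scale.

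The tricarboxylic acid cycle was shifted upward with a list mean of 0.77 ± 0.25 (adjusted p = 3.73e-07, and adjusted p = 0.263 with an estimated correlation). Of 15 members, icd, for isocitrate dehydrogenase, rose 2.80-fold (log2 ratio 1.48 ± 0.19) and 14 did not pass over all genes. Adjusted over the list alone, 9 were higher and 1 was lower. The succinate dehydrogenase genes sdhC, sdhB and sdhA had log2 ratios of 1.42 ± 0.37, 1.36 ± 0.43 and 1.31 ± 0.69. The lower member was fumC, named after its value was seen, which encodes the iron-independent fumarase and had a log2 ratio of -1.13 ± 0.42.

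Genes of the glyoxylate shunt and acetate use had a list mean of 0.78 ± 0.32 (adjusted p = 9.6e-05, and adjusted p = 0.332 with an estimated correlation). This list did not pass with fry (adjusted p = 0.0576). Of 9 members, actP, the acetate permease gene, rose 3.48-fold (1.80 ± 0.49), and 3 passed adjusted over the list alone. aceA, for isocitrate lyase, had a log2 ratio of 1.20 ± 0.36, acs, for acetyl-CoA synthetase, 1.36 ± 0.61, and aceB, for malate synthase, 0.78 ± 0.63. prpD, which encodes 2-methylcitrate dehydratase of propionate breakdown and was in no list, rose 6.65-fold (2.73 ± 0.96), from an interior signal above background on 1 of 4 images.

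Uptake of peptides was shifted upward, with a list mean of 1.24 ± 0.13 over 11 genes (adjusted p = 2.6e-08, and adjusted p = 0.121 with an estimated correlation). The dipeptide permease genes dppB and dppD rose 4.82-fold (2.27 ± 0.85) and 4.44-fold (2.15 ± 0.48), and oppA, for the oligopeptide-binding protein, rose 3.41-fold (1.77 ± 0.40). The other 8 members did not pass, among them oppD at 1.59 ± 0.49, and 9 members passed adjusted over the list alone. glnQ, for the ATPase of glutamine uptake, rose 3.40-fold (1.76 ± 0.23), and glnH, for its binding protein, had 1.35 ± 0.35 without passing. Their list, nitrogen limitation, was not shifted (mean 0.24 ± 0.24 over 23 genes, adjusted p = 0.101).

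Sugar transport and catabolism was shifted by a smaller mean, 0.38 ± 0.03 over 58 genes (adjusted p = 0.000432, and adjusted p = 0.123 with an estimated correlation). The median of its members was 0.18, with 37 above 0 and 21 below. Of these, 6 rose, 52 did not pass, and 11 passed adjusted over the list alone. mglB, for the galactose-binding protein, rose 4.49-fold (2.17 ± 0.43) and mglA, for the ATPase of the same transporter, 3.40-fold (1.77 ± 0.48). malE, for the maltose-binding protein, rose 4.42-fold (2.14 ± 0.75), and malT, the activator of the maltose genes, 3.65-fold (1.87 ± 0.33). Of these, malE and mglA were named after their values were seen, and malE was left out by the filter on control spots. The galactitol phosphotransferase genes gatA and gatB rose 3.48-fold (1.80 ± 0.21) and 3.35-fold (1.74 ± 0.36).

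Outer membrane porins had a list mean of 1.11 ± 0.20 over 11 genes (adjusted p = 4.19e-06, and adjusted p = 0.121 with an estimated correlation). Beside ompW, the porin gene ompF (3.39-fold, 1.76 ± 0.28) and the list member nmpC (5.52-fold, 2.46 ± 0.95) rose. So did ompT (3.20-fold, 1.68 ± 0.39), which encodes an outer membrane protease and no porin. The other 7 members did not pass. Adjusted over the list alone, 5 were higher and 1, ompX, was lower (log2 ratio -0.73 ± 0.37), a gene named after its value was seen.

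Amino acid catabolism had a list mean of 0.34 ± 0.23 over 26 genes (adjusted p = 0.0158, and adjusted p = 0.442 with an estimated correlation). It did not pass with fry (adjusted p = 0.196). tnaA, for tryptophanase, which splits tryptophan into indole, pyruvate and ammonia, rose 5.95-fold (2.57 ± 0.69) and was the single member to pass over all genes or over the list alone. dadA, for D-amino acid dehydrogenase, had 0.89 ± 0.78, ansB, for asparaginase II, 0.54 ± 0.37 and gabD 0.57 ± 0.49. This list, the cytochrome oxidases and the ribosomal proteins lost their call in the one-colour replicates alone, and cell division and murein lost it in the two-colour replicates alone.

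Ribosomal protein genes had a list mean of 0.35 ± 0.24 over 54 genes (adjusted p = 4.37e-06, and adjusted p = 0.442 with an estimated correlation), with 45 members above 0. The list did not pass with fry (adjusted p = 0.175). No member passed over all genes or over the list alone (limma, 13 members at an unadjusted p under 0.05, 12 higher and 1 lower). rplD had a log2 ratio of 1.21 ± 0.35, rplW 0.97 ± 0.34, rplV 0.93 ± 0.30 and rpsS 0.81 ± 0.25. The lower member was rpsI at -1.04 ± 0.36, named after its value was seen. Cell division and murein synthesis had a list mean of 0.35 ± 0.25 over 27 genes (adjusted p = 0.017, and adjusted p = 0.298 with an estimated correlation). Fry did not call this list either (adjusted p = 0.192). Again no member passed (limma, 5 at an unadjusted p under 0.05). minD and minC, which place the division site, had 1.34 ± 0.50 and 0.76 ± 0.13, ftsI, for a septal transpeptidase, 1.25 ± 0.66, and mraY 1.04 ± 0.97. Outside all lists, mepK, for a murein endopeptidase, rose 5.98-fold (2.58 ± 1.02) and cspA, for the major cold-shock protein, rose 5.57-fold (2.48 ± 0.53).

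The phage shock genes, which respond to damage of the inner membrane, were the 1 list shifted downward. Its mean was -0.75 ± 0.25 over 7 genes, all of them below 0 (adjusted p = 0.000189, and adjusted p = 0.251 with an estimated correlation). No member passed over all genes (limma, 5 at an unadjusted p under 0.05), and 5 passed adjusted over the list alone. pspG had a log2 ratio of -1.24 ± 0.66, pspA, the effector of the response, -0.92 ± 0.27, pspD -0.90 ± 0.27 and pspB -0.68 ± 0.19. Single genes with the smallest p in this direction that did not pass were yeaY at -1.89 ± 0.64, aroM at -1.45 ± 0.29, yeeZ at -1.26 ± 0.18 and kdpA, for a potassium-transporting ATPase, at -1.34 ± 0.38 (adjusted p between 0.0518 and 0.0841). They were followed by csdE at -1.19 ± 0.27, intR at -1.34 ± 0.56, yhhS at -1.47 ± 0.73, yddM at -1.17 ± 0.41 and exuT, for a hexuronate transporter, at -1.24 ± 0.50. crr, for the glucose-specific enzyme IIA, had -1.06 ± 0.27 and ybhL -1.03 ± 0.22. In the perimeter kdpA stood above background on 1 of 4 images, and yeaY, aroM, intR and yhhS on 2 of 4. There csdE, pspG, pspA, pspD and pspB did so on 3 of 4. Ratios of these genes depend on the signal floor and are not exact.

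**Figure D1:**
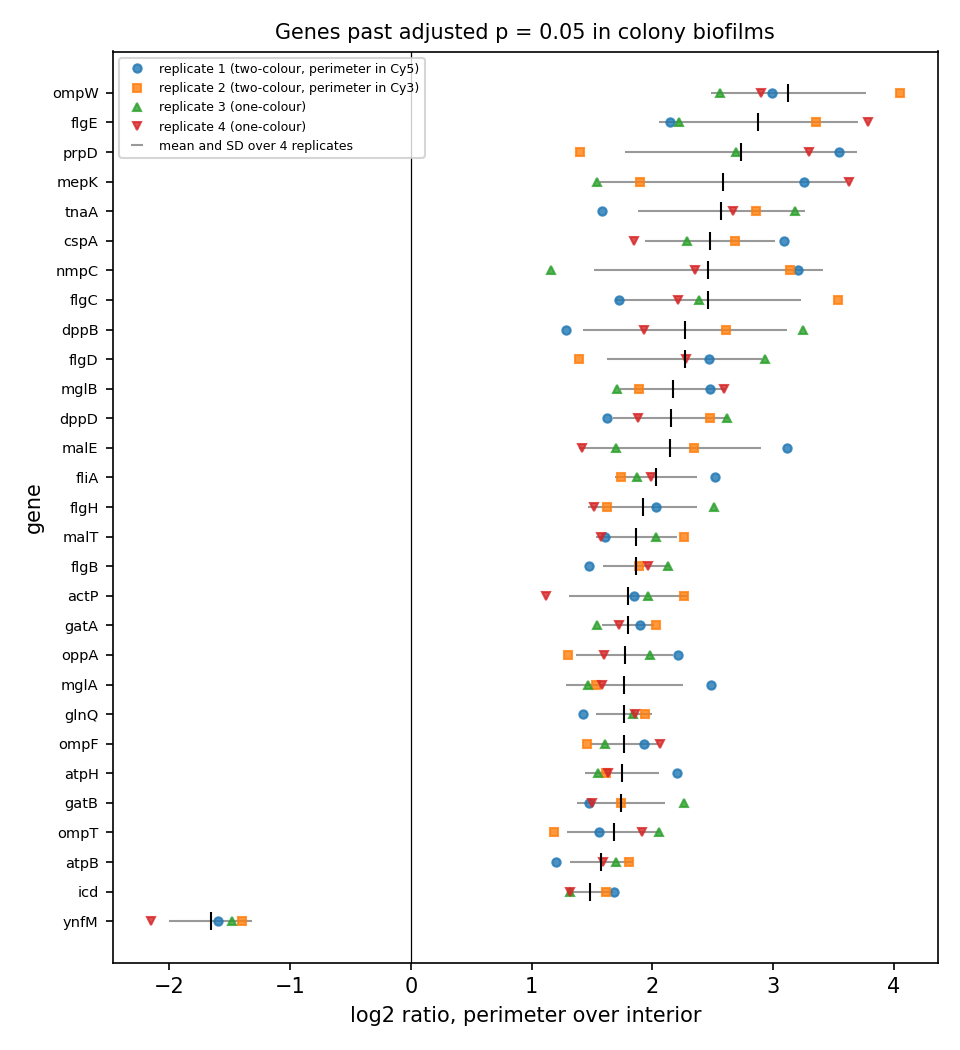
Log2 ratio of perimeter over interior (x axis, log2 units) for each of the 29 genes past the threshold (y axis). Points are the 4 replicates, ticks the means and lines 1 SD; 28 genes lie above 0 and ynfM lies below, at -1.66.

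**Figure D2:**
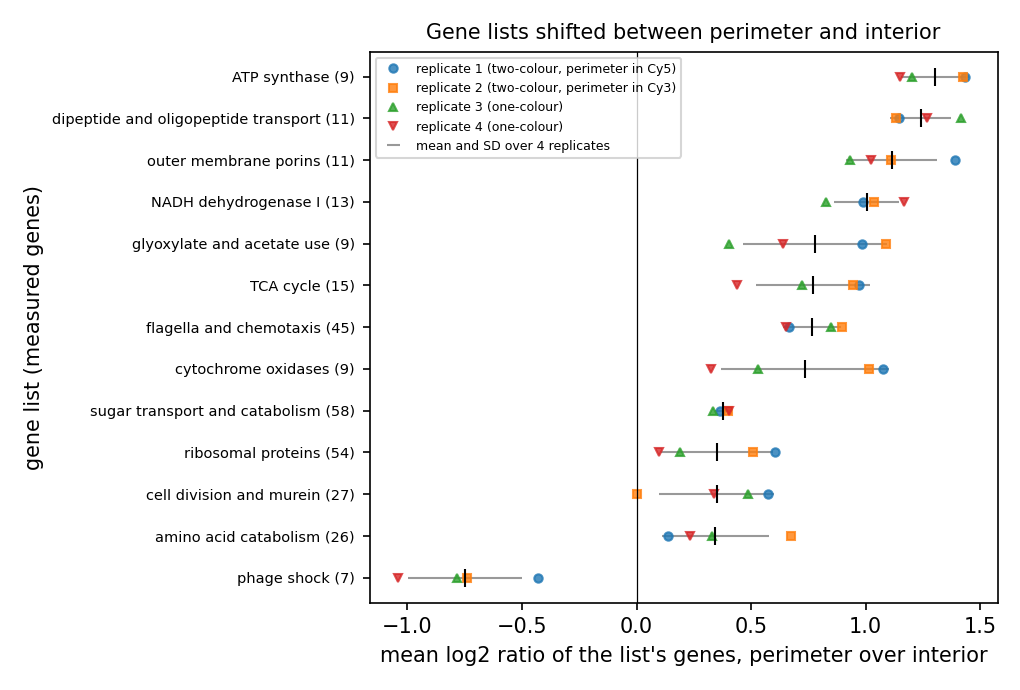
Mean log2 ratio of perimeter over interior (x axis, log2 units) of the 13 shifted gene lists (y axis, with the number of measured genes). Points are the list means of the 4 replicates, ticks their means and lines 1 SD; the means run from -0.75 for phage shock to 1.30 for ATP synthase.

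The 32 other lists did not pass and are called not shifted, with adjusted p from 0.0651 to 0.922 and list means from -0.29 to 0.42. Not passing does not exclude a shift. Recovery of a list shift was simulated for the flagella list alone, and not for smaller lists. The RpoS general stress genes of stationary phase had a mean of -0.08 ± 0.15 over 29 genes (adjusted p = 0.472); katE, for a catalase, stood at 0.73 ± 0.26 and glgS at -0.68 ± 0.31. Anaerobic respiration had -0.09 ± 0.13 over 39 genes (adjusted p = 0.633), with glpB at 1.32 ± 0.65 and glpA at 0.83 ± 0.31, both of glycerol-3-phosphate oxidation. Fermentation had -0.28 ± 0.24 over 9 genes (adjusted p = 0.173), with pflB, for pyruvate formate-lyase, at -0.90 ± 0.91 and hycE at -0.61 ± 0.58. Nucleoid proteins had 0.35 ± 0.16 over 10 genes (adjusted p = 0.0651), with hupB at 1.25 ± 0.38 and hns at 0.61 ± 0.37.

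Among lists of matrix and adhesion, curli had a mean of 0.42 ± 0.38 over 7 genes (adjusted p = 0.185), with csgG at 0.71 ± 0.54 and csgE at 0.83 ± 1.26. Colanic acid had -0.29 ± 0.52 over 22 genes (adjusted p = 0.108), with wzc at -0.66 ± 0.67 and wcaJ at -0.65 ± 0.71. Fimbriae and antigen 43 had 0.21 ± 0.34 over 14 genes (adjusted p = 0.784), with fimA, for the main fimbrial subunit, at 1.87 ± 1.22 and fimC at 1.07 ± 0.66. Cellulose and poly-GlcNAc had -0.12 ± 0.60 over 7 genes (adjusted p = 0.907), with bcsA at -1.09 ± 1.15 and bcsF at 0.60 ± 0.39. Indole and biofilm-associated regulators had 0.13 ± 0.15 over 16 genes (adjusted p = 0.777), tnaA being the member that passed and bssS, a biofilm regulator, standing at -1.10 ± 0.34.

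Lists of stress and nutrient limitation gave similarly small means. Acid resistance had 0.15 ± 0.18 (adjusted p = 0.285), with gadC at 0.81 ± 0.60 and gadW at 0.59 ± 0.43. Heat shock chaperones and proteases had 0.12 ± 0.13 (adjusted p = 0.536), with groS at 1.01 ± 0.62 and groL at 0.85 ± 0.39. Osmoprotection, which holds kdpA, had -0.18 ± 0.14 (adjusted p = 0.472), with proP at -1.41 ± 1.19. Iron acquisition had -0.05 ± 0.15 over 41 genes (adjusted p = 0.742), with entA at 0.89 ± 0.74 and fhuF at 0.55 ± 0.32. The SOS response had -0.17 ± 0.11 (adjusted p = 0.367), with ssb at -0.66 ± 0.34, and phosphate starvation had 0.11 ± 0.27 (adjusted p = 0.787), with ugpA at 1.45 ± 1.14. In arginine and in pyrimidine biosynthesis, carA (1.12 ± 0.62) and carB (1.20 ± 0.71) of carbamoyl phosphate synthesis led the list without passing over all genes. The mean, the median and the direction of the test differed in sign for 5 of the lists not shifted. These were arginine biosynthesis, branched-chain amino acid biosynthesis, cellulose and poly-GlcNAc, fimbriae and antigen 43, and indole and biofilm-associated regulators.

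The test was limma on the log2 ratio of each replicate, and the 29 genes had adjusted p between 0.0410 and 0.0467, close to the threshold. At an unadjusted p under 0.05, 472 genes passed, where chance alone would give 184.1 over both directions together. Of the 472 genes, 288 were higher and 184 lower. Of the 29 genes, 12 stood above background on all 8 images; in the interior flgH and prpD did so on 1 of 4, malE, mepK, dppB, dppD and fliA on 2 of 4, and ompW, flgE, flgC, flgD, tnaA, malT, glnQ, actP and mglA on 3 of 4. In the perimeter ynfM did so on 2 of 4 and fliA on 3 of 4. Folds of genes with a region under background depend on the signal floor and the offset and are not exact. Signal above background does not clear the level of the control spots. The median internal control spot stood between 2.09 and 4.10 times the background. Between 38.5% and 51.4% of the gene probes of an image exceeded the 95th percentile of these spots. Leaving out any 1 of replicates 1 to 4, blocking on hybridisation type, a dye term, the median pixel signal, the authors' table or no filter on faint probes each left 0 genes (limma, between 160 and 515 genes at an unadjusted p under 0.05). With a robust variance fitted to brightness the count was 127. All 29 genes kept their sign in each setting that measured them, which settings that drop or weight replicates could not change. The authors' table measured 9 of the 29.

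The next comparison asked whether the difference between the regions depended on how the RNA was hybridised, 2 dyes on 1 slide or 1 dye on separate slides. No gene differed (limma, 0 of 3682 genes, with 138 at an unadjusted p under 0.05 where chance gives 184.1). Over all genes, r of the two-colour and the one-colour means was 0.315. The 29 genes and 13 lists had the same sign in both formats, and their selection on the mean of the same replicates favours this for both. With hybridisation type as a block 13 lists were shifted, with the two-colour replicates alone 12 of these 13 were, and with the one-colour replicates alone 10 of these 13 and curli. The ribosomal protein list differed, with a mean of 0.56 in the two-colour and 0.14 in the one-colour replicates (difference 0.41, adjusted p = 0.00954, and adjusted p = 0.880 with an estimated correlation). Cytochrome oxidases had means of 1.04 and 0.43 in these formats (adjusted p of the difference = 0.115). Each format held 2 replicates, so a difference had to be large to be detectable. Scan day and scaling also differed between the formats.

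The last comparison asked how well the replicates matched each other across genes. Pearson's r of the log2 ratios ranged from 0.0751, between replicates 1 and 2, to 0.278, between replicates 1 and 3, with a mean of 0.167. Genes are not independent replicates, and these values carry no p. When the genes were divided into 4 classes of equal size by brightness, the mean r was 0.0168, 0.0827, 0.299 and 0.464 from the faintest to the brightest class. The calls fell mostly among bright genes, with 1, 3, 10 and 15 in the same order. In the brightest class lay genes such as cspA, ompF, atpH and gatA, and 23.4% of all genes had the same sign in the 4 replicates, where chance gives 12.5%.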

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

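Tests of the signal floor, the dyes, exchanged labels and scaling were chosen after the results were seen, and so were the label exchanges. Among 128 named genes and 45 lists, 10 genes and 1 list had a replicate far from the others, where chance gives about 1 in 20. In replicate 1 csdE stood at -1.60, atpH at 2.20 and nusB at 3.80, against means of the other replicates of -1.06, 1.60 and 0.87. In replicate 3 yhhS stood at -2.55, atpE at 0.99, dadA at -0.26 and glnH at 1.87, against -1.11, 1.75, 1.28 and 1.18. In replicate 4 wzc stood at -1.66 and fhuF at 1.03, against -0.33 and 0.39, and in replicate 2 csgE stood at -1.05 against 1.45. The fatty acid degradation list had a mean of 0.0752 in replicate 3 against 0.331.

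The ribosomal protein list differed between hybridisation types by 0.41 (adjusted p = 0.00954, and adjusted p = 0.880 with an estimated correlation; fry, adjusted p = 0.398). Its means were 0.56 in the two-colour and 0.14 in the one-colour replicates, above 0 in 4 of 4 replicates. The scan day coincides with the type, and the 2 cannot be told apart. The scaling also differed by type, loess for the two-colour and quantile for the one-colour replicates, and its part in this difference was not tested. The Arabidopsis control spots, which the comparisons do not use, reached 67.4% of the median gene-probe signal in the interior image of replicate 3 and at least 49.7% elsewhere.

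The replicates matched poorly over all genes (mean r 0.167). A floor of unspecific signal may explain this: the mean r of the brightest 921 genes exceeded that of the faintest 921 by 0.447. Bias between the dyes is argued against among the brightest 921 genes alone, because r of the replicates with opposite dyes differed from that of the one-colour replicates by -0.00230. In the 3 fainter classes r was lower with opposite dyes (0.229 against 0.363, -0.0785 against 0.196, and -0.103 against 0.00762 in the faintest), so a dye bias there stays open; the test on the faintest class and its threshold were set after the value was seen. An exchange of the region labels in 1 replicate is argued against, since turning any replicate gave a mean r of at most 0.0498. A biological difference between the pooled biofilms was not tested.

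Of 29 genes, 28 were higher in the perimeter. With other background corrections and scalings at least 89% were higher, but each of these centres the ratios near 0, so scaling stays open; a filter requiring all images gave 78.3%. Lower genes could lie too close to the signal floor to pass: among the brightest 921 genes, 65.1% of those at an unadjusted p under 0.05 were higher, between the bounds set for the test, and 38.5% among the faintest 921. A biological cause, such as the state of the cells at the perimeter, stays open and untested.

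Exchanging the region labels within replicates gives 8 arrangements, too few for a share under 0.05. The labels as given called 29 genes, 28 higher and 1 lower, and the highest of the others called 0 (limma, at most 208 genes at an unadjusted p under 0.05, against 472). For lists the values were 13 and 9. As large a result came in 1 of 8 arrangements, the labels as given, for each of these counts.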

How the results depend on the processing

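The removal of marked spots and the filter on control spots were chosen after seeing the data; the other alternatives were planned. The genes that pass depended on the processing. Against 29 genes (28 higher, 1 lower), no background correction gave 100 (89 and 11), plain subtraction 53 (50 and 3), a filter requiring all images 92 (72 and 20), the control-spot filter 113 (100 and 13), a robust variance trend 127 (109 and 18), an adjusted p under 0.1 74 (68 and 6), and no replicate block 17 (17 and 0). Median centring left 0 lower genes of 21. The median pixel signal, no filter on dim probes, the dye term, the hybridisation block, the two-colour or one-colour replicates alone, the authors' table, both removals of marked spots, and leaving out any of replicates 1 to 4 (lowest and highest 0) gave 0 genes, 0 higher and 0 lower (limma, 145 to 515 genes at an unadjusted p under 0.05). The dye term and the hybridisation block leave each mean ratio as it was, so those calls were lost to the spread and the residual degrees of freedom. Leaving out a replicate also removes a degree of freedom; otherwise the cause was not tested. All 29 genes kept their sign in each setting that measured them, and no result reversed. Their sign was the same in the 4 replicates, so settings that drop, weight or block replicates could not turn it. The authors' table and both removals of marked spots measured 9 of the 29. The control-spot filter measured 26 of the 29, without ynfM, prpD and malE. The filter requiring all images measured 12 and also left these genes out.

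Of the 13 lists, 11 could be tested with a filter requiring all images, and 8 passed. With either removal of marked spots, and with the values of the authors, 8 could be tested and 5 passed. With fry 8 passed and with an estimated correlation 0 (camera, 8 at an unadjusted p under 0.05). Those that did not pass fry were glyoxylate and acetate use, cytochrome oxidases, ribosomal proteins, cell division and murein, and amino acid catabolism. Their adjusted p with fry was between 0.0576 and 0.196. On simulated data of independent genes a list shift of 0.5 was recovered in 0 of 20 runs with an estimated correlation, 11 with fry and 20 with the preset. In the measured data the estimated correlation was 0.159 for ribosomal proteins and for the TCA cycle and 0.227 for cytochrome oxidases. It was below 0 for ATP synthase (-0.0343), peptide transport (-0.0678), porins (-0.0299) and sugar transport (-0.0118). For these lists the call was not lost to a positive correlation between genes. The other shifted lists had estimates above 0, from 0.00535 for cell division and murein upward. The simulation held no correlation between genes and no other shift size. It cannot tell whether a call lost with an estimated correlation speaks against a shift. Amino acid catabolism was called in 15 of 22 settings, cell division and murein in 14 of 22 and sugar transport in 19 of 22. Flagella and chemotaxis and ribosomal proteins were each called in 21 of 22, and cytochrome oxidases in 18 of 19. All kept their sign. Up to 7 lists not called changed sign in a setting. Agreement was 0.238 without background correction and 0.238 in the authors' table, against 0.167. The authors' table holds 43.7% to 49.0% of the spots of a replicate, so its value covers other genes and is not a like comparison. Low signal over background (3.6 to 6.84) limits the faint genes.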

Other observations

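The tests on cspA, on CRP and on operons were chosen after related values were seen; the test on slide position was written beforehand. The rise of cspA (log2 ratio 2.48) may have come from cooling of the membranes before the RNA was stabilised. The other 16 cold-shock genes had a mean of 0.0422 ± 0.28 (SD over 4 replicates), but they went both ways. cspB (1.34 ± 1.03) and ynaE (0.74 ± 0.28) were higher and raiA (-0.66 ± 0.20) and rnr (-0.59 ± 0.17) lower, each at an unadjusted p under 0.05 without passing, so cooling stays open. Cross-hybridisation from paralogs stays open too, since the highest of the 8 measured paralogs, cspB at 1.34, overlaps cspA within 2 standard errors of each. The conditions of both tests, and of those on CRP and on scaling, were changed after their values were seen.

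A candidate explanation for the sugar and acetate genes was a wider activation through CRP, the regulator of carbon catabolite control. A set of 33 measured genes activated by CRP had a mean log2 ratio of -0.133 ± 0.07, above 0 in 0 of 4 replicates (camera, adjusted p = 0.564). The set was chosen from outside the fixed lists, apart from tdcA, and so leaves out passing genes such as malE, mglB, gatA, actP and tnaA. Its members went both ways, 14 above 0 and 19 below, with cstA at 1.25, whose value had been seen before the test. The test leaves activation through CRP open.

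Genes next to each other on the chromosome had similar ratios, with r of 0.285 over 2927 pairs against 0.019 for genes 50 apart. The difference of 0.266 fits a hypothesis of shared operons, which may carry part of the signal in the gene lists. Spots next to each other on the slide had r of at most 0.0368, which argues against printing position.

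The filters that leave out faint genes had more lower genes, which are named here after their values were seen. With signal above background on all images 20 genes were lower, all with the same sign in 4 replicates, and 10 of them were also lower under the control-spot filter. The lower gene of the main test, ynfM, was measured under neither filter. Of the 20, fumC stood at -1.13 ± 0.42, bssS at -1.10 ± 0.34, crr at -1.06 ± 0.27 and pgi, for phosphoglucose isomerase, at -0.88 ± 0.34. A filter requiring all images also removes genes whose signal fell to background.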
